A study of Mus musculus with 16 samples.

How the data were processed

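RNA was measured in group 2 innate lymphoid cells (ILC2), a tissue-resident lymphocyte population, sorted from the duodenum of untreated mice kept free of specific pathogens. Per the labels' protocols, the mice were of the C57BL/6 strain and 6 to 10 weeks old, the first 5 cm of the small intestine were digested with Liberase TM, cells were enriched on Percoll and sorted by flow cytometry, and libraries were made with the Nextera XT kit, which does not mark the strand of origin. The sort gate was not given in the sources used here. The 16 libraries fell into 4 genotypes of 4 libraries each, taken from the sample titles: wild type (WT), Alox5 KO, Il25 KO and St2 KO. Every mouse carried the Smart13 reporter at Il13, and the Il25 KO and St2 KO mice also carried the Yarg reporter at Arg1, which the WT and Alox5 KO mice did not. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries.

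The authors deposited 1 table of counts per gene for the whole series, not scaled for depth or gene length. Per the submitters' processing notes, STAR 2.4.2a, HTSeq 0.4.1, Picard 1.134, FastQC 0.11.3 and the mouse build GRCm38 were used. Their settings, the annotation release and any removal of duplicate reads were not given in the sources used here. The table had 53471 gene rows. After 6 rows with a repeated gene identifier were dropped, 53465 genes were kept, of which 25978 had a count in at least 1 library. Rows for 3433 genes had no symbol in the table and held 0.184% of the counts. No column lay outside the 16 libraries. Of the identifiers, 99.6% were in the GENCODE annotation used here for gene positions and exon lengths on GRCm38, and protein-coding genes held 97.0% of the counts.

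The total gene count per library ranged from 2086864 to 3216937, with a median of 2625205.5, and between 15490 and 16529 genes were detected per library. Abundant genes followed depth weakly: 122 tested genes had at least 0.5 reads per exonic base on average and the highest reached 3.06, so fold changes of the densest genes may be compressed. In regions of repeated or near-identical sequence, such as pseudogenes, the counting can split or lose reads, and without strand information reads of overlapping genes cannot be told apart.

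The sample codes in the description labels carried 3 letter pairs. TS held replicates 1 and 2 of all 4 genotypes, TT held replicates 3 and 4 of WT and Alox5 KO, and TY held replicates 3 and 4 of Il25 KO and St2 KO. What the letters stand for was not given. The 4 TY libraries had 982 to 1682 counts of Xist, the non-coding RNA of the inactive X chromosome, and at most 2 of the Y-linked gene Ddx3y, and the 12 other libraries had at most 7 and at least 709. The TY libraries were therefore read as female and the others as male.

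Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, trimmed-mean (TMM) scaling and the default expression filter over the 4 genotypes, which kept 11742 genes. Genotype and sample-code set were terms in 1 model of all 16 libraries, which left 10 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Depth-scaled counts (CPM) used the TMM-scaled totals. The 35 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested, which left 31 lists, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. List members were also counted after adjustment over the list alone.

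The groups, the tests, the gene lists, the sample-code term, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named here as chosen later. The rule named the targeted and reporter genes, up to 10 higher and 10 lower genes of largest fold change among called genes with an average log2 CPM of at least 3 and an established symbol, up to 4 called members per list, and a panel of 20 ILC2 genes. The newer mode of edgeR's quasi-likelihood fit was used because the legacy mode had been listed as the alternative; the counts of calls under both modes had been seen before this was settled. 3 alternatives were added after the data were seen: leaving out 3 libraries with low plasma cell transcripts, leaving genes of at least 0.5 reads per exonic base out of the list tests, and leaving Arg1 out of the lists.

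The procedure was tested on simulated counts for the real genes with known changes in 3 runs per comparison. For Alox5 KO against WT (11417 genes), 55.4% of 2-fold and 86.3% of 4-fold changes were recovered, and 8.4% of calls were false. For Il25 KO against WT (11419 genes) the values were 50.5%, 80.7% and 6.9%. For St2 KO against WT (11416 genes) they were 47.9%, 81.9% and 11.2%, and for Il25 KO against St2 KO (11409 genes) 61.6%, 85.1% and 8.1%. The false share was thus above the nominal level in this mode. In legacy mode it was 5.0%, 5.0%, 5.9% and 3.3% in the same order. In 20 simulated runs of the list test for St2 KO against WT over 11742 genes, the shifted list was called 20 times and other lists 0 of 580 times.

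Alternatives were the fit without the sample-code set, fits with the replicate number as a block, fits of the compared groups or of single sets alone, each library left out, size factors of DESeq2 1.42.0, upper-quartile scaling, other filters, DESeq2 and limma voom with sample weights as tools, edgeR's legacy mode and other thresholds. No library fell under the planned depth limit, so that alternative removed 0 libraries. Ratios of summed counts had exact 95% intervals, which cover counting error only; reads without molecular identifiers are not independent molecules. Where a group had 0 counts, a floor of 3 counts over the group was used. Correlations across genes describe genes, which are not independent replicates. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 4.91 to 10.2 over the 24 pairs, and each was counted as a separate sample. Figures were drawn with matplotlib 3.10.9.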

Results

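RNA was sequenced from group 2 innate lymphoid cells (ILC2) sorted from the mouse duodenum, in 4 genotypes of 4 libraries each: WT, Alox5 KO, Il25 KO and St2 KO. Alox5 encodes 5-lipoxygenase, the enzyme that starts leukotriene synthesis, Il25 encodes a cytokine made by tuft cells of the epithelium, and ST2, encoded by Il1rl1, is the receptor of the cytokine IL-33. The comparisons with WT ask which transcripts of resting ILC2 differ when each signal is missing. Total gene counts per library ranged from 2086864 to 3216937 with a median of 2625205.5, and the median standard error of a log2 fold change was between 0.213 and 0.268 in the 3 comparisons with WT and in Il25 KO against St2 KO. All fold changes are from the edgeR quasi-likelihood model with sample-code set as a term, and adjusted p-values are Benjamini-Hochberg values over 11742 genes. Values in CPM are means ± SD with n = 4 libraries, and log2 fold changes are given ± SE.

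The targeted and reporter genes were read first. Alox5 (ENSMUSG00000025701, GRCm38 chromosome 6, 116410077 to 116461178) fell from 96.2 ± 33.5 CPM in WT to 9.95 ± 3.51 CPM in Alox5 KO, a log2 fold change of -3.28 ± 0.396 (adjusted p = 0.000411). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes arginase 1, fell from 335.4 ± 36.8 CPM in WT to 21.5 ± 3.50 CPM in Il25 KO and 22.2 ± 7.59 CPM in St2 KO. Both of those genotypes carry the Yarg reporter at Arg1 and WT does not, so the change follows the reporter allele as well as the knockout. Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415) had 171.9 ± 38.8 CPM in the libraries labelled St2 KO and 215.4 ± 35.6 CPM in WT, which did not differ by the test (log2 fold change -0.25 ± 0.271, adjusted p = 0.8898). Against the 290.0 ± 102.6 CPM of Il25 KO the log2 fold change of Il25 KO over St2 KO was 0.74 ± 0.219, which did not pass over all genes (adjusted p = 0.1407) and passed adjusted over each of 3 lists alone (adjusted p of 0.02231 to 0.04018). Counts over all exons of a gene do not show whether a deletion removed part of it, so the St2 KO label could not be checked from these counts. Il25 (ENSMUSG00000040770, chromosome 14, 54932695 to 54935837) had 0 counts in all 16 libraries, which checks nothing.

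**Figure D1:**
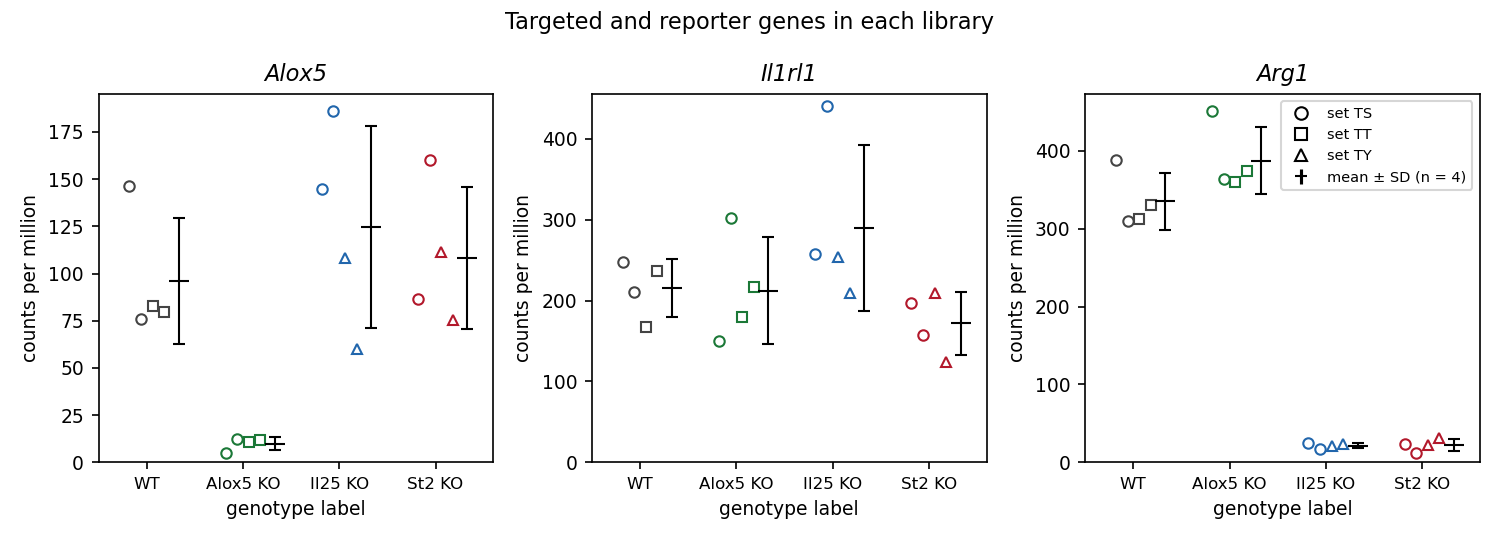
CPM of Alox5, Il1rl1 and Arg1 in each library by genotype, with the mean and SD of 4 libraries per genotype. Alox5 was low in the Alox5 KO libraries, Arg1 was low in Il25 KO and St2 KO, and Il1rl1 overlapped between St2 KO and WT.

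In Alox5 KO against WT, 12 genes passed the threshold, 4 higher and 8 lower, with 842 genes at an unadjusted p under 0.05. If no gene differed, a share of about 0.05 of the tested genes would lie there by chance. Wnt5b, a secreted Wnt ligand encoded near Alox5 on chromosome 6 (119432531 to 119544347), rose from 1.83 ± 1.87 to 36.8 ± 12.8 CPM (log2 fold change 4.29 ± 0.521, adjusted p = 0.0001356). Ctse, which encodes the protease cathepsin E, rose from 63.6 ± 13.4 to 238.1 ± 27.1 CPM (1.92 ± 0.212, adjusted p = 0.0001563), and Gpr18, a lipid-sensing receptor, rose from 15.5 ± 3.89 to 80.8 ± 21.9 CPM (2.39 ± 0.302, adjusted p = 0.0006263). Rnpep, which encodes an aminopeptidase, fell from 128.2 ± 13.6 to 42.6 ± 7.84 CPM (-1.57 ± 0.171, adjusted p = 0.0001563). Csrp1 also rose (1.04 ± 0.194), and Btg2, an antiproliferative immediate early gene, fell (-0.58 ± 0.099). Haspin, a mitotic kinase, Ly6d and Fam222b were lower as well, with log2 fold changes of -2.94, -3.91 and -2.07. Ctse, Rnpep, Btg2 and Csrp1 all lie on chromosome 1. All 12 changes had the same direction within the TS and the TT libraries, both of which entered the fit. The calls of Derl3, Haspin, Ly6d, Btg2, Prg2, Fam222b and Csrp1 were each lost without at least 1 single library. Over the 16 fits with 1 library left out, Csrp1 was lost in 13, Prg2 in 9 and Derl3 in 2. Without Alox5 KO replicate 2 the count was 6, and without replicate 3 or 4 it was 7. It was 5 in edgeR's legacy mode, 53 with DESeq2 and 3 without the 3 libraries with low plasma cell transcripts (Alox5 KO 1, Alox5 KO 2 and St2 KO 1).

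Among the fixed lists in this comparison, 3 of 31 passed with the preset correlation and 0 with an estimated correlation or with fry. B and plasma cell markers fell (camera adjusted p = 3.889e-05; adjusted p = 0.8427 with an estimated correlation; median log2 fold change -1.01), with 11 of 14 members below 0. Derl3, of the endoplasmic reticulum of secretory cells, passed over all genes (-4.07 ± 0.620), and 3 members passed adjusted over the list alone. The low values lay in Alox5 KO 1 and Alox5 KO 2, where the mean log2 CPM of the list was 1.937 and 3.855, against 4.209 to 5.915 in the libraries outside these and St2 KO 1. Cell cycle genes fell (adjusted p = 0.0007758; adjusted p = 0.8427 with an estimated correlation), with 29 of 37 members below 0, 0 past the threshold over all genes and 4 adjusted over the list alone. The mean log2 CPM of the list was 2.946 in Alox5 KO 1 and 3.927 to 4.491 in the other Alox5 KO libraries, against 4.036 to 5.213 in WT. Ribosomal protein genes rose (adjusted p = 3.247e-05; adjusted p = 0.8427 with an estimated correlation; median 0.119), with 0 of 52 members past over all genes or adjusted over the list alone, and Alox5 KO 4 stood apart, with a mean log2 CPM of 5.983 against at most 5.720 in the other Alox5 KO libraries and 5.663 in WT. Prg2, which encodes a granule protein of eosinophils, also passed (-4.74 ± 0.888, adjusted p = 0.03723). Of the eicosanoid list, Alox5 itself passed. No gene of the ILC2 panel passed, and the receptors Cysltr1 and Ltb4r1 had log2 fold changes of 0.16 and -0.10.

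In Il25 KO against WT, 49 genes passed, 16 higher and 33 lower, with 1092 at an unadjusted p under 0.05. Lgals3, which encodes galectin 3, rose from 2.19 ± 2.69 to 74.1 ± 16.7 CPM (log2 fold change 5.82 ± 0.715, adjusted p = 2.206e-05), and lies on chromosome 14 as Il25 does. AA467197, Tmem87a and Adat2 rose with log2 fold changes of 3.38, 1.94 and 2.25. Pla2g7, which encodes a secreted phospholipase that degrades platelet-activating factor, fell from 71.1 ± 45.3 to 3.06 ± 2.78 CPM (-5.07 ± 0.881, adjusted p = 0.006352). Tph1, the enzyme that starts serotonin synthesis, fell from 26.9 ± 14.0 to 5.37 ± 6.60 CPM (-3.87 ± 0.772, adjusted p = 0.02304), with a call that was lost without any 1 of WT replicate 2, Il25 KO replicates 1, 2 and 4 and St2 KO replicates 1 and 4. The fitted changes of Tph1, Fst and Klrb1b depended on the sample-code term, with values of -2.40, 1.43 and -0.41 without it, none past the threshold. Pecam1, an adhesion molecule, fell from 148.9 ± 19.7 to 64.2 ± 14.0 CPM (-1.56 ± 0.193, adjusted p = 0.0002973). Cd79b, a part of the B cell receptor, fell (-1.07 ± 0.160, adjusted p = 0.0019), and Klrb1b, a lectin-like receptor gene of the natural killer gene complex, fell (-0.81 ± 0.157, adjusted p = 0.02227). Fst, Slc24a3, Rgcc, Tanc2 and H60b rose by log2 fold changes of 2.76, 2.71, 1.06, 0.73 and 2.00, and Ppfibp2, Rpgrip1, Slc52a3, Haspin and Psmb5 fell, with log2 fold changes of -2.96, -3.37, -4.85, -3.46 and -0.90. Alpk3 had 144 counts in WT and 1 in Il25 KO, a ratio of 146.7 (95% counting interval 25.9 to 5835). Rpl26 (-2.89), Pcna-ps2 (5.14) and Hmgb1-ps8, with a ratio of 131.4 (95% counting interval 23.2 to 5231), have pseudogenes or overlapping genes, so their values are uncertain. Set TS, the only one that holds both groups, gave 9 genes when fitted alone, all among the 49. The calls of Slc52a3, Haspin, Fst, Klrb1b, Tanc2, Slc24a3, Rgcc, Psmb5 and Hmgb1-ps8 were also each lost without at least 1 single library. Psmb5 and Hmgb1-ps8 were each lost in 15 of the 16 fits with 1 library left out. Rgcc was lost in 10 of them, and Slc52a3 and Haspin in 1 each. The count was 31 without WT replicate 2 and 26 without the 3 libraries low in plasma cell transcripts. It was 9 in a fit of these groups alone, where the contrast also rests on the TS libraries through the sample-code term.

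Among the lists in Il25 KO against WT, 5 of 31 passed with the preset correlation and 0 with an estimated correlation or with fry. The count was 2 without WT replicate 2 and 3 without WT replicate 4 or Alox5 KO replicate 2. Dissociation and immediate early genes were higher in 22 of 24 members (adjusted p = 0.001662; adjusted p = 0.6333 with an estimated correlation; median 0.262), with 0 members past the threshold over all genes and 3 adjusted over the list alone. Type 2 effector genes were lower (adjusted p = 0.01416; adjusted p = 0.7391 with an estimated correlation); Arg1, the reporter locus, and Tph1 passed over all genes, and 1 higher and 2 lower members passed adjusted over the list alone. The list's median log2 fold change was -0.264 and its mean -0.669, with 6 members above 0 and 9 below 0. Arg1, at -4.22, follows the reporter allele as well as the knockout, and Tph1 was at -3.87. The mean log2 CPM of the list was 5.010 and 5.321 in Il25 KO 1 and 4 and 6.170 and 6.079 in Il25 KO 2 and 3, against 6.031 to 6.362 in WT. Lipid uptake and storage genes were higher (adjusted p = 0.01416; adjusted p = 0.39 with an estimated correlation; median 0.366), with 0 members past over all genes and 2 adjusted over the list alone. Interferon response genes were lower (adjusted p = 0.01416; adjusted p = 0.7224 with an estimated correlation), as were cell cycle genes (adjusted p = 0.01416; adjusted p = 0.8058 with an estimated correlation). Interferon response values were 4.970 and 4.988 in Il25 KO 1 and 2 and 5.477 and 5.476 in Il25 KO 3 and 4, against 5.140 to 5.605 in WT. The mean log2 CPM of the cell cycle list was 2.66 to 2.78 in Il25 KO 2, 3 and 4 and 4.41 in Il25 KO 1. No gene of the ILC2 panel passed. Nmur1, the receptor of the neuropeptide neuromedin U, had -0.52 ± 0.126 (adjusted p = 0.1222), and Klrg1, a surface receptor of mature ILC2, had -0.40 ± 0.106 (adjusted p = 0.1729).

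In St2 KO against WT, 35 genes passed, 13 higher and 22 lower, with 880 at an unadjusted p under 0.05. Zfp36, which encodes an mRNA-destabilising protein, fell from 514.8 ± 44.1 to 100.8 ± 24.97 CPM (log2 fold change -2.33 ± 0.157, adjusted p = 8.176e-08). The NF-kB inhibitor gene Nfkbia fell from 707.2 ± 31.4 to 301.2 ± 8.52 CPM (-1.23 ± 0.112, adjusted p = 4.614e-06), and Nfkbid and Nfkbiz of the same family fell by 2.45 and 0.95 on the log2 scale. Csf2, which encodes the cytokine GM-CSF, fell from 265.9 ± 13.2 to 74.2 ± 16.2 CPM (-1.80 ± 0.179, adjusted p = 1.268e-05). Ptgs2, the inducible prostaglandin synthase, fell from 126.8 ± 26.4 to 7.45 ± 4.30 CPM (-3.48 ± 0.567, adjusted p = 0.007879), with a call that was lost without WT replicate 1, St2 KO replicate 1 or St2 KO replicate 2. Cd28, a T cell costimulatory receptor encoded on chromosome 1 (60716800 to 60773359), rose from 15.9 ± 5.30 to 269.8 ± 42.4 CPM (4.26 ± 0.374, adjusted p = 1.282e-06). Gadd45b, Map3k8, Ier5, Nr4a1, Fosb, Btg2 and Tnfaip3 fell, with log2 fold changes of -1.38, -1.91, -1.28, -0.86, -1.04, -0.69 and -0.75. Cd69, Mir155hg, Ly6d and Igtp fell, with values of -1.17, -2.25, -3.99 and -0.46. Tmem87a, AA467197, Adat2, Ptdss1, Ctse, H60b and Mterf3 rose by 1.63, 2.81, 2.21, 0.89, 1.36, 1.64 and 0.72. Pcna-ps2 (4.58) and Hmgb1-ps8, with a ratio of 149.2 (95% counting interval 26.3 to 5939), are uncertain for the reason given above. Set TS fitted alone gave 26 genes, of which 21 were among the 35. The calls of Pcna-ps2, Ier5, Ly6d, Tnfaip3, Btg2, Cd69, Ctse, Mir155hg, H60b, Hmgb1-ps8, Mterf3 and Igtp were also each lost without at least 1 single library. Of the 16 fits with 1 library left out, Mterf3 was lost in 15, Igtp in 14 and H60b in 13. Hmgb1-ps8 was lost in 11, and Ier5 and Ly6d in 1 each. The count was 19 without WT replicate 1, 23 without WT replicate 2 and 21 without the 3 libraries low in plasma cell transcripts.

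**Figure D2:**
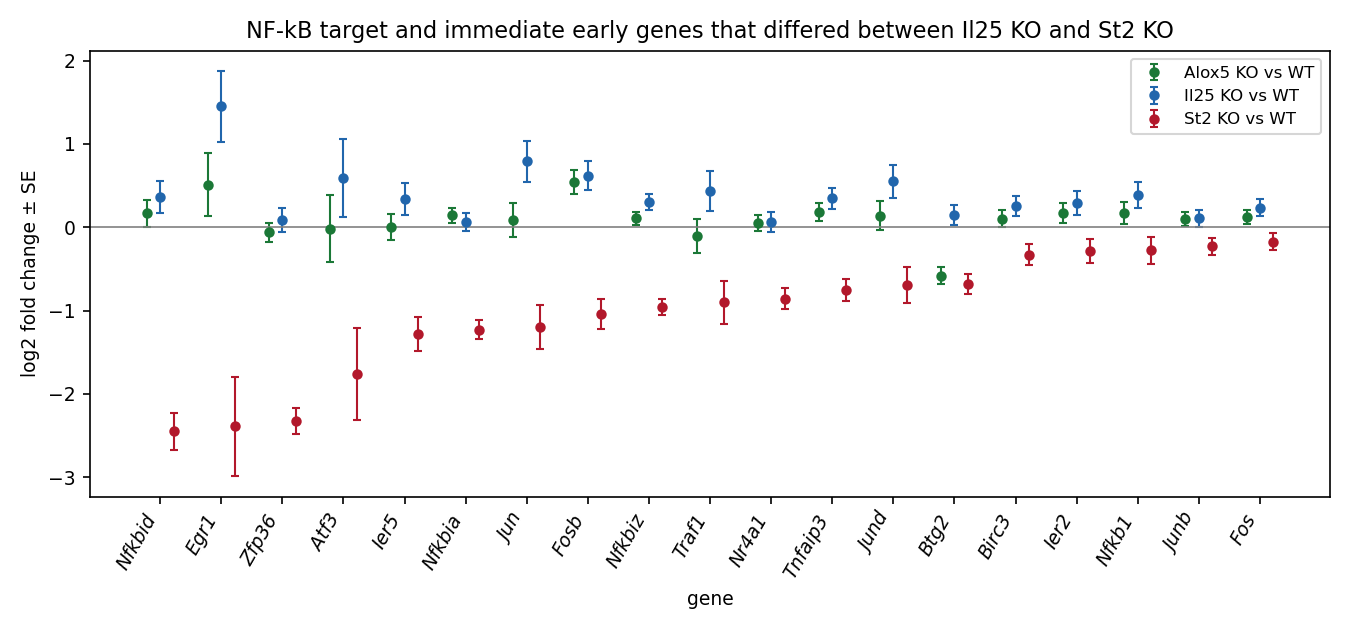
Log2 fold change ± SE against WT in Alox5 KO, Il25 KO and St2 KO for the 19 genes of the NF-kB and immediate early lists that passed in Il25 KO against St2 KO, from 4 libraries per genotype. The St2 KO points for Zfp36 (-2.33) and Nfkbia (-1.23) lie below 0, and those of Il25 KO lie near or above 0.

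NF-kB targets were lower in St2 KO in 20 of 23 members (camera adjusted p = 8.044e-12; adjusted p = 0.06857 with an estimated correlation; median -0.35), with 4 lower over all genes and 8 adjusted over the list alone. Dissociation and immediate early genes were lower in 18 of 24 members (adjusted p = 7.948e-11; adjusted p = 0.06796 with an estimated correlation), with 5 past over all genes and 10 adjusted over the list alone. The mean log2 CPM of that list was 6.80 to 6.99 in the 4 St2 KO libraries and 7.29 to 7.91 in the 12 others. Type 2 effector genes were lower in 14 of 15 members (adjusted p = 5.192e-10; adjusted p = 0.06857 with an estimated correlation), with Csf2 and Arg1 past over all genes and 4 adjusted over the list alone. STAT5 targets and negative regulators were lower in 21 of 24 members (adjusted p = 1.004e-05), and it was the 1 list that also passed with an estimated correlation (adjusted p = 0.01938). Of its members only Tnfaip3, which is also in the NF-kB list, passed over all genes, and 5 passed adjusted over the list alone. NFAT and calcium response genes were lower (adjusted p = 3.398e-06; adjusted p = 0.06796 with an estimated correlation), as were interferon response genes (2.923e-05; adjusted p = 0.1474 with an estimated correlation). In all, 14 of 31 lists passed with the preset correlation and 7 with fry. B and plasma cell markers were lower in 14 of 14 members (adjusted p = 7.97e-05; adjusted p = 0.2481 with an estimated correlation; median -1.23), and macrophage and dendritic markers had a median of -1.08 without passing. Of the St2 KO libraries, St2 KO 1 had the lowest B and plasma cell value, 2.099. Mitochondrially encoded genes were lower in 7 of 7 members (adjusted p = 7.97e-05; adjusted p = 0.2688 with an estimated correlation). ILC1 and NK, arginine and polyamine, class II, eicosanoid and ribosomal protein genes were lower and lipid uptake and storage genes higher, each lost with an estimated correlation (adjusted p of 0.07886 to 0.7934). Of the arginine and polyamine list, with a median of -0.088, only Arg1, the reporter locus, passed over all genes. Of the ILC2 panel, Nfkbia, Csf2 and Tnfaip3 passed, and Areg, which encodes amphiregulin, did not (-1.86 ± 0.537, adjusted p = 0.3373).

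**Figure D3:**
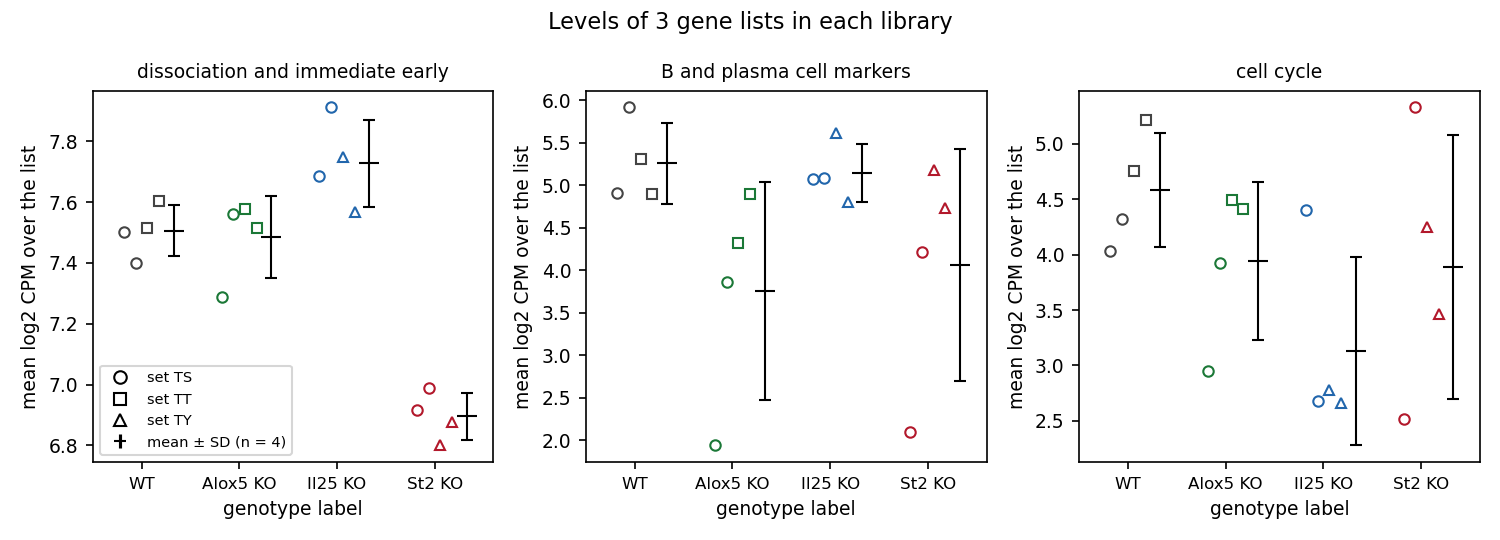
Mean log2 CPM per library of the dissociation and immediate early, B and plasma cell, and cell cycle lists, by genotype. The St2 KO libraries lie between 6.80 and 6.99 in the first, and single Alox5 KO and St2 KO libraries are low in the second.

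Il25 KO and St2 KO carry the same reporter alleles, and in their direct comparison 146 genes passed, 100 higher in Il25 KO and 46 lower, with 1321 at an unadjusted p under 0.05. Zfp36 was higher in Il25 KO by 2.41 ± 0.133 (adjusted p = 2.392e-09), with 539.6 ± 21.2 against 100.8 ± 24.97 CPM. Egr1, an immediate early transcription factor gene, had 131.9 ± 49.5 against 9.03 ± 6.78 CPM (3.84 ± 0.425, adjusted p = 2.922e-05). Nfkbia and Csf2 were higher in Il25 KO by 1.29 ± 0.093 and 1.54 ± 0.152, and Ptgs2 by 4.09 ± 0.492. Fosb, Ier5, Nr4a1, Zc3h12a, Pim1, Cd69, Bhlhe40, Ccl1, Nfkbiz, Nfkbid and Tnfaip3 were also higher, with log2 fold changes of 1.66, 1.63, 0.92, 1.82, 1.86, 1.23, 0.78, 2.54, 1.26, 2.81 and 1.10. Lgals3 (5.41), Ly6d, Arl5c and Slc24a3 were higher in Il25 KO, as were Eps8l1, Dusp8, Ifi27l2a, Isg15, Odc1, Itgae and Dgat1, and Cd28 was lower (-4.80 ± 0.287, adjusted p = 2.392e-09). Pecam1, Rpl26, Rpgrip1, Irak3, Ppfibp2, Slc52a3, Slc30a2, Arhgef10l, Psmb5, Cd79b and Kmo were lower, and Alpk3 had 168 counts in St2 KO and 1 in Il25 KO (ratio 148.0, 95% counting interval 26.2 to 5879). All 146 changes had the same direction within TS, and all 140 with a value within TY, and both sets entered the fit. The calls of Ifi27l2a, Arhgef10l, Ccl1, Psmb5, Cd79b, Kmo, Dusp8, Odc1, Isg15, Itgae and Dgat1 were each lost without at least 1 single library. Itgae and Dgat1 were each lost in 11 of the 16 fits with 1 library left out, and Ifi27l2a in 1. The count was 80 without St2 KO replicate 2, 81 without Il25 KO replicate 3, 84 without St2 KO replicate 4 and 85 without Il25 KO replicate 2, and 90 without the 3 libraries low in plasma cell transcripts.

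Lists gave 13 of 31 past with the preset correlation, 2 with an estimated correlation and 7 with fry. Dissociation and immediate early genes were higher in Il25 KO in 20 of 24 members (adjusted p = 2.601e-21, and 0.01361 as an adjusted p with an estimated correlation), with 12 past over all genes and 17 adjusted over the list alone. NF-kB targets were higher in 21 of 23 members (adjusted p = 2.899e-15; adjusted p = 0.0591 with an estimated correlation), with 7 past over all genes, and 12 higher and 1 lower adjusted over the list alone. STAT5 targets and negative regulators were higher (adjusted p = 0.000371, and 0.03062 as an adjusted p with an estimated correlation), with 3 past over all genes and 8 adjusted over the list alone. Heat shock genes passed as higher (adjusted p = 0.03888; adjusted p = 0.2939 with an estimated correlation), where the median was 0.08 and the mean -0.001. Cell cycle genes were lower (adjusted p = 0.001313; adjusted p = 0.5407 with an estimated correlation), with a mean log2 CPM of 2.513 in St2 KO 1 and 3.465 to 5.33 in the other St2 KO libraries, against 4.408 in Il25 KO 1 and 2.658 to 2.776 in the other Il25 KO libraries. Ribosomal protein genes were higher (2.595e-05; adjusted p = 0.5174 with an estimated correlation), as were B and plasma cell markers (0.02361; adjusted p = 0.5174 with an estimated correlation). Of the 14 B and plasma cell markers 12 lay above 0, the 1 member past over all genes, Cd79b, was lower, and 1 higher and 1 lower passed adjusted over the list alone. Type 2 effector, NFAT, cytokine receptor, eicosanoid and mitochondrially encoded genes were higher and neighbours of Il25 lower, each lost with an estimated correlation (adjusted p of 0.2939 to 0.5936). The list count was 4 without Il25 KO replicate 2.

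Alox5 KO against Il25 KO gave 46 genes, 26 higher and 20 lower in Alox5 KO, and Alox5 KO against St2 KO gave 57, 36 higher and 21 lower. The first count was 19 without Alox5 KO replicate 1, and the second was 27 without St2 KO replicate 2 and 33 without Alox5 KO replicate 2. Across all 4 genotypes together, 137 genes passed. Il25 KO and St2 KO shared 8 calls against WT in the same direction, Arg1, Adat2, AA467197, Tmem87a, Pcna-ps2, H60b, Hmgb1-ps8 and Gm26740. With WT split so that each comparison had its own WT libraries, 5 and 6 calls were shared. The parts were fitted in 1 model with common sample-code terms, so they are not independent. Alox5 KO and St2 KO shared Ctse, Btg2 and Ly6d, and Alox5 KO and Il25 KO shared Haspin. With WT split these pairs shared 0 and 0 calls, and 1 and 0. With WT split, the correlation of log2 fold changes across genes was 0.322 and 0.278 for Il25 KO and St2 KO, against 0.028 to 0.073 for the pairs with Alox5 KO. These correlations are across genes, which are not independent replicates, and Il25 KO and St2 KO also share the TY set, its sex and the Yarg reporter. With all WT libraries they were 0.585 for Il25 KO with St2 KO, and 0.378 and 0.355 for the pairs with Alox5 KO. In 40 simulations of unchanged groups with all WT libraries, the means were 0.664, and 0.4065 and 0.4059. The design alone thus gives the higher value for Il25 KO with St2 KO, so it does not show that these knockouts resemble each other. The split was not simulated.

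**Figure D4:**
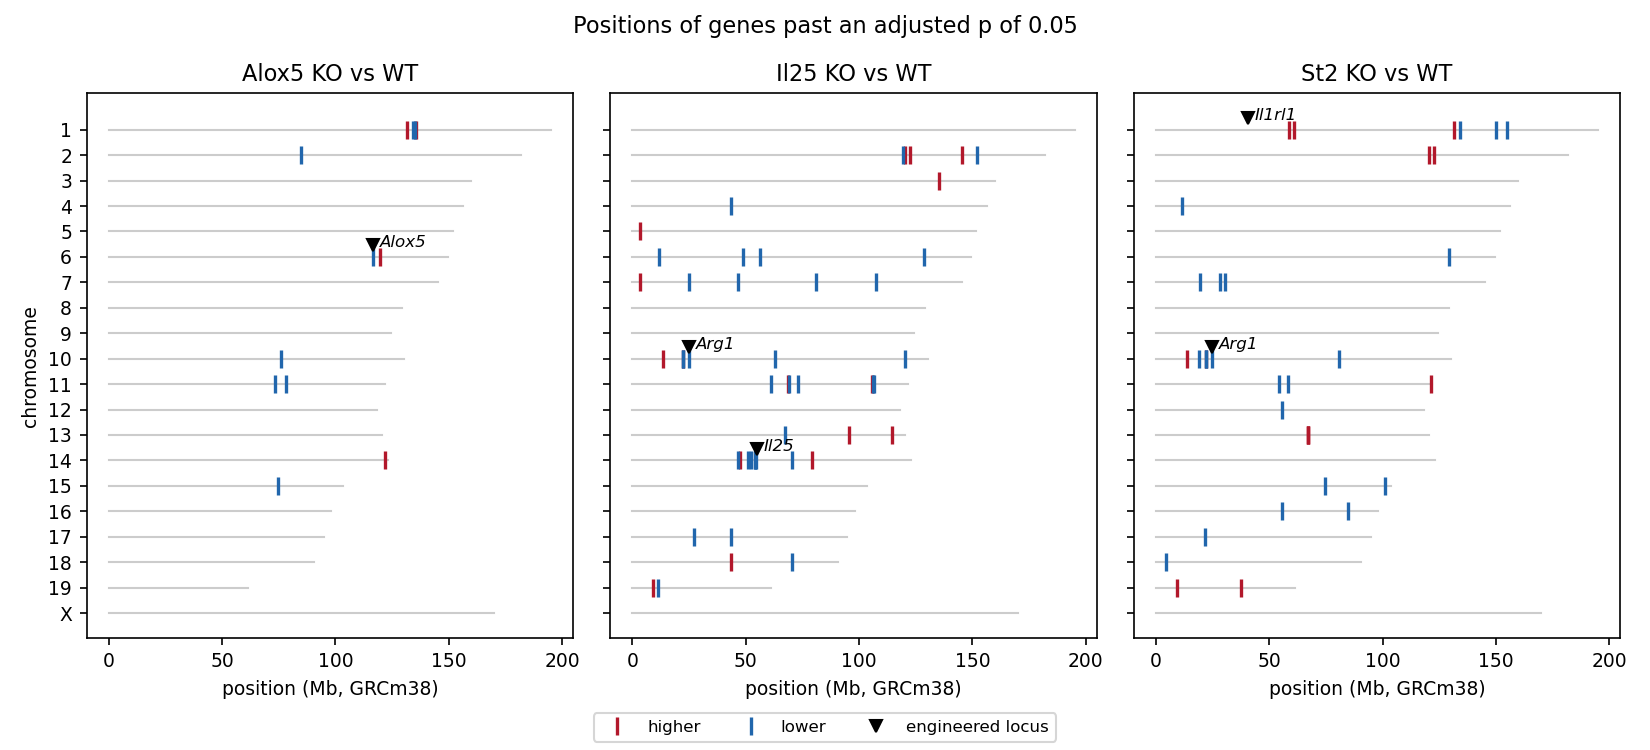
Chromosome positions on GRCm38 of genes past the threshold in each comparison, with the engineered loci marked. In Il25 KO against WT, 12 of 48 called genes other than Arg1 lay within 20 Mb of Arg1 or Il25.

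Called genes were also placed on the genome, after their positions had been seen, with the engineered genes themselves left out. In Il25 KO against WT, 12 of 48 calls lay within 20 Mb of Arg1 or Il25, where 2.89% of tested genes lie (Fisher's exact one-sided p = 7.588e-09). Lgals3, Psmb5 and Rpgrip1 lay near Il25, and Adat2, H60b and Hmgb1-ps8 near Arg1. In St2 KO against WT, 5 of 34 lay within 20 Mb of Arg1 (Fisher's exact one-sided p = 3.441e-05), among them Tnfaip3, and 1 lay within 20 Mb of Il1rl1, which is not more than tested genes by the test (Fisher's exact one-sided p = 0.3565). Cd28 lay just beyond that distance from Il1rl1. In Alox5 KO against WT, Wnt5b was the 1 of 11 within 20 Mb of Alox5, which is not more than tested genes by the test (Fisher's exact one-sided p = 0.1588). In Il25 KO against St2 KO, 8 of 146 calls lay within 20 Mb of Il25, where 1.77% of tested genes lie (Fisher's exact one-sided p = 0.004445). Lgals3, Rpgrip1 and Psmb5 were among them. Within 20 Mb of Il1rl1 lay 2 of the 146 (Fisher's exact one-sided p = 0.5632).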

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

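The tests of positions near engineered loci, of other clusters and of calls in TS alone, and the test with marker lists as terms, were chosen only after the results they address had been seen; the other tests were written before.

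Of 183 groups of 4 libraries examined, 15 had a library far from the rest of its group, with a gap above the 95% critical value of Dixon's test, and chance alone gives about 1 in 20 groups. The total count of Alox5 KO 4 was low, 2086864. Alox5 was 4.743 CPM in Alox5 KO 1 and 146.2 CPM in WT 1, each apart from the rest of its genotype, and Haspin was 4.348 CPM in Alox5 KO 1. In 4 of the 15 the other 3 libraries had 0 counts, so any count would meet the critical value and these show nothing; 11 remain without them. The 4 were Alpk3 at 0.3625 CPM in Il25 KO 4 and Hmgb1-ps8 at 0.3625 CPM in Il25 KO 4 and 0.3366 CPM in St2 KO 1, each 1 count, and Slc52a3 at 3.842 CPM in Il25 KO 2. Nfkbid was 111.4 CPM in St2 KO 4, Nfkbia 753.6 CPM in WT 1, Ctse 59.96 CPM in St2 KO 4 and Igtp 304.9 CPM in WT 2. Cd28 was 25.85 CPM in Il25 KO 3, and Eps8l1 and Itgae were 8.857 and 17.71 CPM in St2 KO 4.

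The difference between Alox5 KO and WT itself differed between the sets TT and TS for 4 immunoglobulin-related genes of 10923 tested, by an interaction term with Benjamini-Hochberg adjustment. The log2 difference was 5.854 for Igha (adjusted p = 5.676e-07), 5.163 for Jchain (0.0004303), 3.316 for Igkc (0.0006415) and 6.044 for Iglv1 (0.004959). Between the sets TY and TS, Il25 KO against St2 KO differed for 0 of 11069 genes in edgeR. An unadjusted p under 0.05 was found for 515, about the share that chance alone gives. No other tool was run on this interaction.

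The first pattern was that NF-kB and immediate early genes were lower in the libraries labelled St2 KO than in WT, with a median of -1.044 over the 9 called genes, against -0.349 and -0.202 over all tested members of the 2 lists, which did not pass with an estimated correlation (adjusted p = 0.06857 and 0.06796). The 114 other dense genes had a median of -0.172 (quartiles -0.213 and -0.115). The called genes fell further, but they were picked by passing in this same comparison, so this does not decide on a count ceiling. The quartiles hold the median of the whole immediate early list, so a ceiling stays open for that list. Both lists still passed with the preset correlation when dense genes were left out. The median of the called genes was -1.256 in St2 KO against Il25 KO within TY and -1.325 within TS. A difference between sample-code sets alone would not give that contrast. Both sets entered the fit that picked these genes, and the contrast holds no WT library. It therefore does not decide on sets for St2 KO against WT. For the 6 called genes on chromosomes without Arg1 or Il1rl1, the tables argue against linked DNA acting on genes beside it. Tnfaip3 was the 1 called gene within 20 Mb of Arg1 or Il1rl1, where 2.42% of tested genes lie. Fewer cells of another type stays open: B and plasma cell and macrophage markers reached -1.226 and -1.079, which met the prediction first written for it, and with macrophage markers as a term the mean difference from WT over all tested members went from -0.818 ± 0.198 to -0.514 ± 0.159 for NF-kB targets and from -0.49 ± 0.085 to -0.396 ± 0.089 for the immediate early list. With a library left out and any of 10 marker lists as the term, the upper 95% limits reached 0.039 and -0.108, above the bounds of -0.409 and -0.245, and types without a list were not tested. Loss of ST2 may account for the pattern as a hypothesis only: cell composition and stress during dissociation cannot be told apart from it, the latter as heat shock genes had a median of -0.107 with quartiles of -0.15 and 0.136, against -0.202 for the immediate early list, and age and strain DNA acting at a distance were not tested.

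The second pattern was that calls of Il25 KO and St2 KO against WT lay near engineered loci: 14 of 75 called genes other than the engineered ones lay within 20 Mb of Arg1, Il25 or Il1rl1, against 4.17% of tested genes (Fisher's exact p = 2.184e-06). DNA of another strain linked to those loci may account for it but was not shown, since that count is the pattern itself, and in Alox5 KO, outside the pattern, the excess near Alox5 was not past the threshold with 1 of 11 calls (Fisher's exact p = 0.1588). Calls farther away formed 32 pairs within 10 Mb of each other against 18.86 on average in 10000 random draws (permutation p = 0.0154), so strain DNA elsewhere is a candidate explanation of those. In the male TS libraries alone, 4 of 31 calls lay there against 4.21% of tested genes (Fisher's exact p = 0.03966), among them Lgals3 and Adat2. The pattern's genes not called there still differed from WT within TS. In Il25 KO the log2 fold changes were -0.77 ± 0.17 (Cnih1), -0.77 ± 0.18 (Ppp3cc), -0.82 ± 0.23 (Psmb5), -3.35 ± 0.70 (Rpgrip1), 1.85 ± 0.40 (H60b), -1.06 ± 0.165 (Trdv4), -2.30 ± 0.48 (Gm26782) and -8.28 ± 1.48 (Hmgb1-ps8). In St2 KO they were -0.80 ± 0.14 (Tnfaip3) and 1.70 ± 0.44 (Gm37760). The calls of the full fit rest mainly on TS, the only set that holds WT and these knockouts, so differences within TS were likely. These values therefore do not decide on a difference between sets, of which TY is female. Genes that neighbour each other can also change together for biological reasons, which was not tested.

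The third pattern was that the count of the densest genes followed the library total weakly. For genes with at least 0.5 reads per exonic base the median slope on log scales was 0.287, against 1.319 for genes under 0.05. Removal of duplicate reads may account for it, but the slope of the sparse genes lay outside 0.8 to 1.2, so the test does not decide. Within genotypes the slopes were 0.414 and 1.274, and no biological explanation was tested.

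Other divisions of the same libraries into groups of the same sizes were fitted. No other division reached the gene count of Alox5 KO against WT (12, reached by 1 of 34 divisions, the real one, highest other 5). The same held for Il25 KO against WT (49, 1 of 35, 4) and St2 KO against WT (35, 1 of 35, 14). It also held for Il25 KO against St2 KO (146, 1 of 34, 15), Alox5 KO against St2 KO (57, 1 of 35, 1) and any genotype (137, 1 of 60, 8). The real division always counts, so 1 is the smallest number possible, and the shares were not adjusted over the comparisons. They argue against chance for each count taken alone but do not exclude it. For Il25 KO and St2 KO against WT, other divisions also mixed libraries of sets TT and TY, which differ in sex. For Alox5 KO against Il25 KO, 2 of 35 divisions gave at least 46 genes. The other one, with Alox5 KO 2 and 4 set with Il25 KO 2 and 3, reached 52 and does not follow the sample-code sets. For gene lists, no other division reached the counts of St2 KO against WT (14, 1 of 35, 12) and Il25 KO against St2 KO (13, 1 of 34, 12). The margins were narrow: without 1 library the counts fell to as low as 10 and 4, below the 12 of another division. Other divisions did reach the list counts of Alox5 KO against WT (3, 12 of 34, 5) and Il25 KO against WT (5, 14 of 35, 10).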

How the results depend on the processing

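Leaving out 3 libraries with low plasma cell transcripts (Alox5 KO 1 and 2, St2 KO 1), leaving dense genes out of the lists and leaving Arg1 out of the lists were tests chosen only after the results were seen; the others were planned. No named gene reversed under any alternative, where a reversal was counted for genes called in either fit. Over named genes, 5169 settings kept the side of the threshold, 519 lost the call and 13 gained it. The 5169 include genes called in neither fit, for which a change of direction was not counted. Of 104 calls of named genes, 30 held under every alternative and 42 were lost without some single library. Those that held under every alternative were 1 of 12 for Alox5 KO against WT and 4 of 24 for Il25 KO. They were 14 of 27 for St2 KO and 11 of 41 for Il25 KO against St2 KO. Over lists, 688 settings kept the call and 150 lost it. At the depth and number of libraries at hand, 47.9% to 61.6% of simulated 2-fold changes were recovered; depth was not varied.

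Counts of genes are given for each alternative that moved them by more than 1.5 times; where no reason is given, the cause was not tested. Without the sample-code set, Il25 KO against WT gave 95, St2 KO against WT 58, Alox5 KO against Il25 KO 81 and Alox5 KO against St2 KO 122. With the replicate number as a block in its place, the counts were 20 for Alox5 KO against WT, 98 for Il25 KO, 66 for St2 KO, 105 and 144 for Alox5 KO against Il25 KO and St2 KO, and 242 for any genotype; with both terms Alox5 KO against WT gave 21. Pairing of libraries by replicate number was weak at most: of 24 pairs 3 had a correlation above 0.1 (range -0.079 to 0.197). Still, 7 of 16 libraries were closest to one of their own number, so some pairing is not excluded. With the compared groups alone, Alox5 KO against WT gave 22, Il25 KO 9, Il25 KO against St2 KO 96, and Alox5 KO against Il25 KO and St2 KO 14 and 31. For Il25 KO against WT and for Alox5 KO against Il25 KO and St2 KO, only TS holds both groups. Those fits therefore take the contrast from the TS libraries, as the fit of TS alone does. In TS alone, the counts were 3, 9 (Il25 KO), 33 (Il25 KO against St2 KO), 12, 19 and 42 for any genotype, and in TY alone Il25 KO against St2 KO gave 30.

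In edgeR's legacy mode Alox5 KO against WT gave 5. Counts under both modes had been seen before the mode was settled, and the simulated share of false calls was lower in legacy mode (3.3% to 5.9%) than in the mode used (6.9% to 11.2%). At a threshold of 0.10 the counts were 21 for Alox5 KO against WT, 230 for Il25 KO against St2 KO and 78 for Alox5 KO against Il25 KO. With an absolute log2 fold change of at least 1, Il25 KO against St2 KO gave 97. DESeq2 gave 53, 82 and 67 against WT (Alox5, Il25, St2 KO), 246 for Il25 KO against St2 KO, 105 and 100 for Alox5 KO against Il25 KO and St2 KO, and 299 for any genotype. Limma voom with sample weights gave 5 (Alox5 KO), 29 (Il25 KO), 88 (Il25 KO against St2 KO) and 30 (Alox5 KO against Il25 KO). Without the 3 libraries, the counts were 3, 26 and 21 against WT, 90, 2 and 11 between knockouts (Il25 with St2, Alox5 with Il25, Alox5 with St2), and 83 for any genotype, and 2 lists passed for Il25 KO against WT.

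List counts fell to 0, 0, 1 and 2 with an estimated correlation (Alox5, Il25, St2 KO against WT, Il25 KO against St2 KO), and fry gave 0, 0, 7 and 7. With WT split between the comparisons, shared calls were 0 for Alox5 and Il25 KO in 1 split part, 0 and 0 for Alox5 and St2 KO, and 5 for Il25 and St2 KO in 1 part.

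With 1 library left out, the ranges were 6 to 20 for Alox5 KO against WT, 31 to 53 for Il25 KO, 19 to 45 for St2 KO, 80 to 168 for Il25 KO against St2 KO, 19 to 45 and 27 to 64 for Alox5 KO against Il25 KO and St2 KO, and 95 to 164 for any genotype. The ranges of list counts were 2 to 4, 2 to 7, 10 to 15 and 4 to 14. Counts moved by over 1.5 times without WT 1 (St2 KO 19), WT 2 (St2 KO 23, Il25 KO 31), Alox5 KO 1 (Alox5 with Il25 19), Alox5 KO 2 (Alox5 KO 6, Alox5 with St2 33), Alox5 KO 3 and 4 (Alox5 KO 7 and 7) and Il25 KO 1 (Alox5 KO 20). For Il25 KO against St2 KO they moved without Il25 KO 2 (85), Il25 KO 3 (81), St2 KO 2 (80) and St2 KO 4 (84), and Alox5 with St2 KO moved without St2 KO 2 (27). Lists of Il25 KO moved without WT 2 (2), WT 4 (3) and Alox5 KO 2 (3), and those of Il25 KO against St2 KO without Il25 KO 2 (4). The planned depth exclusion removed 0 libraries and moved nothing. DESeq2 gave no adjusted p for 228 genes in Alox5 KO against WT.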

Other observations

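The cluster test of positions in Alox5 KO was chosen after the positions had been seen. Plasma cell transcripts varied between libraries of the same genotype. Jchain, which encodes the joining chain of secreted IgA and IgM, had 5 and 85 counts in Alox5 KO 1 and Alox5 KO 2 and 98 in St2 KO 1, and at least 1085 in each other library. Igkc, the immunoglobulin kappa constant gene, had 56, 151 and 129 counts in the same libraries and 858 to 984 in the others.

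In Alox5 KO against WT, the 10 called genes farther than 20 Mb from Alox5 formed 7 pairs within 10 Mb of each other, against 0.4387 on average in 10000 random draws (permutation p = 0.0001, the smallest these draws can give). Ctse, Btg2, Rnpep and Csrp1 on chromosome 1 made up part of them. No explanation of this cluster was tested.

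The genes called in both Il25 KO and St2 KO against WT included Arg1 and its neighbours Adat2, H60b and Hmgb1-ps8. On principal components of the log2 CPM values, the first 2 components held 13.4% and 12.7% of the variance.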
